A study of Mus musculus with 6 samples.

How the data were processed

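Chromatin carrying ubiquitylated histone H2B (H2Bub) was measured by chromatin immunoprecipitation and sequencing in C2C12, a mouse myoblast cell line that fuses into myotubes when serum is withdrawn. Per the labels, growing myoblasts (MB) were harvested at about 40% confluency in 10% fetal bovine serum, and myotubes (MT) after 96 h, or 4 days, in 2% horse serum with a medium change at day 2. The cell type label reads C2C12, whereas the source names write C1C12. There were 3 libraries per group. Chromatin was digested with micrococcal nuclease (MNase), mostly to mononucleosomes, and an H2Bub antibody was used, per the labels. The labels give each of the 6 libraries its own antibody lot number; the numbers are consecutive in sample order, so it is uncertain whether they record different lots, and if they do the lot could not be separated from the sample. Input, spike-in and H3K4me3 libraries were not analysed here. The labels give the libraries replicate numbers but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

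The authors deposited 1 file per library with the chromosome, position and strand of each mapped read, on genome build mm9 per the submitters' processing notes. They also deposited 1 list of peaks per group, with no score per peak. The aligner, read length, mapping filters, peak caller, its threshold, any control and the pooling of libraries for the peak lists are not given in the sources used here. A test of the files found 0 repeated lines, so each position and strand was listed at most once per library, as deposited. Reads on the plus strand preceded those on the minus strand by 99 to 107 bp (median 104 bp), less than a nucleosome length, so the listed minus-strand position was taken as the left end of the read. Coordinates are accurate to about 1 bp, since the files do not state whether positions count from 0 or 1. Because repeated positions were absent, densities in the most enriched regions can be compressed, and more so in the libraries with more reads there. Read counts per region were made here by counting positions, so no count table of the authors was used.

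Reads on chromosomes 1 to 19 and X were counted in peaks, in the merged union of both peak lists (202354 regions) and in consecutive 10 kb windows (250807 with reads). Scaling was by the total reads per library, because scaling on the regions themselves would remove a change that all regions share. The main alternative, called background scaling here, used trimmed mean of M-values (TMM) factors over the 10 kb windows, most of which hold no peak. Tested regions and windows had at least 10 reads at the median library size in at least 3 libraries and at least 15 reads in all. This floor retained 63954 regions and 233817 windows. In fits with 1 library left out, the floor asked for 1 library fewer. The groups were compared with limma 3.58.1 (voom, moderated two-sided test) in R 4.3.3, with Benjamini-Hochberg adjustment over all regions or windows tested and a threshold of 0.05. The regions were defined on these same libraries, so the number of called regions is not independent evidence of a direction. A count model had been planned for files that hold reads with coordinates, as these do. Instead, voom was run on the counts made here, and the planned count-model alternatives were not run. Single values per library were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Overlap of the peak lists was set against 1000 random placements of the MT peaks on their own chromosomes. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

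Named regions and windows were those with the largest log2 fold changes, 5 in each direction, among those past the threshold with a mean of at least 50 reads per library; adjacent windows were counted once. Myoblast domains were MB peaks joined across gaps of up to 3 kb into stretches of at least 10 kb, a grouping chosen after the data were seen. Density relative to local background divides the density of a region by that of windows without peaks within 250 kb. The groups, comparisons and most alternatives were fixed before the data were examined. So were the tests of these comparisons, except that limma voom took the place of the planned count model. Alternatives covered the scaling, a replicate block, each library left out, no floor on low counts and shifted read positions. They also covered the upper 50% of peaks by width, 50 kb windows and other overlap rules. Shifted positions moved plus-strand reads by 75 bp and minus-strand reads by 29 bp, toward the nucleosome centre. Thinning to equal depth, limma-trend, and background scaling combined with the block or without MT replicate 2 were added after the data were seen. The annotation at hand was on another build than mm9 and no conversion was made, so the planned results for genes, 16 gene lists and gene bodies were not made and no gene names are given.

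The libraries held 8767810 to 15903500 reads. In simulated data with the means and depths of the peak regions (63954 features), 67, 67 and 66 regions were changed 1.5-fold, 2-fold and 4-fold. The test recovered 1.5%, 1.5% and 78.8% of them, with 2 false calls. For the windows (233817 features) it recovered 13.4%, 61.2% and 100% at the same fold changes, with 0 false calls. With so few changed features the adjustment was far stricter than in the data, where 63137 regions were called. The simulated shares and false calls therefore do not carry over to the comparisons below. Binomial intervals (95%, Wilson) cover counting error only. Within groups, the libraries shared 3.74 to 4.63 times as many read positions as at nearby shifts, against 4.01 to 4.39 times between groups, so no pair of replicates looked like 1 library deposited under more than 1 name.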

Results

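H2Bub, a mark of transcribed gene bodies, was mapped in 3 libraries of growing C2C12 myoblasts (MB) and 3 libraries of myotubes differentiated for 96 h (MT). The myoblast libraries held 9293327, 10500415 and 15903500 reads, and the myotube libraries 8767810, 9251714 and 14480532. The series asks how H2Bub changes when myoblasts become myotubes. All coordinates are mm9.

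Peaks of H2Bub were far fewer and narrower in the myotube list than in the myoblast list, and formed fewer long stretches. The MB list held 191324 peaks covering 103 Mb, with a median width of 371 bp. The MT list held 25745 peaks covering 7.89 Mb, with a median width of 276 bp. This was a ratio of 7.43 in the number of peaks and 13.1 in the bases covered. MB peaks lay side by side in long domains: 5326 stretches of 10 kb or longer held 84.5% of MB peak bases, the longest spanning 238 kb. The MT list formed 182 such stretches with 15.5% of its peak bases. A list with fewer peaks forms fewer such stretches, and no value matched for peak number was computed. Each list is 1 set per group and the threshold behind it is not given in the sources used here, so the difference between the lists has no replicate error.

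The myotube libraries placed a much smaller share of their reads in MB peaks. The share was 34.4% ± 3.58 in myoblasts (SD, n = 3) and 8.42% ± 1.56 in myotubes (SD, n = 3), a difference of -26.0 percentage points. By library it was 34.0%, 38.1% and 31.0% in myoblasts against 9.42%, 6.63% and 9.20% in myotubes. Relative to the sequence outside all peaks, read density in MB peaks was 12.3 ± 1.96 times as high in myoblasts and 2.15 ± 0.43 times in myotubes. Regions in both lists held 7.12% ± 0.83 of myoblast reads and 1.74% ± 0.563 of myotube reads. Even the MT peaks as a set held more myoblast reads (2.64% ± 0.275) than myotube reads (1.34% ± 0.298). The regions found only in the MT list went the other way, with 0.226% ± 0.0157 of myoblast reads and 0.511% ± 0.0288 of myotube reads. Each of these differences had the smallest p that 3 against 3 libraries allow (exact permutation test, two-sided, p = 0.1), so none could reach 0.05, although the groups did not overlap in any of them.

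**Figure D1:**
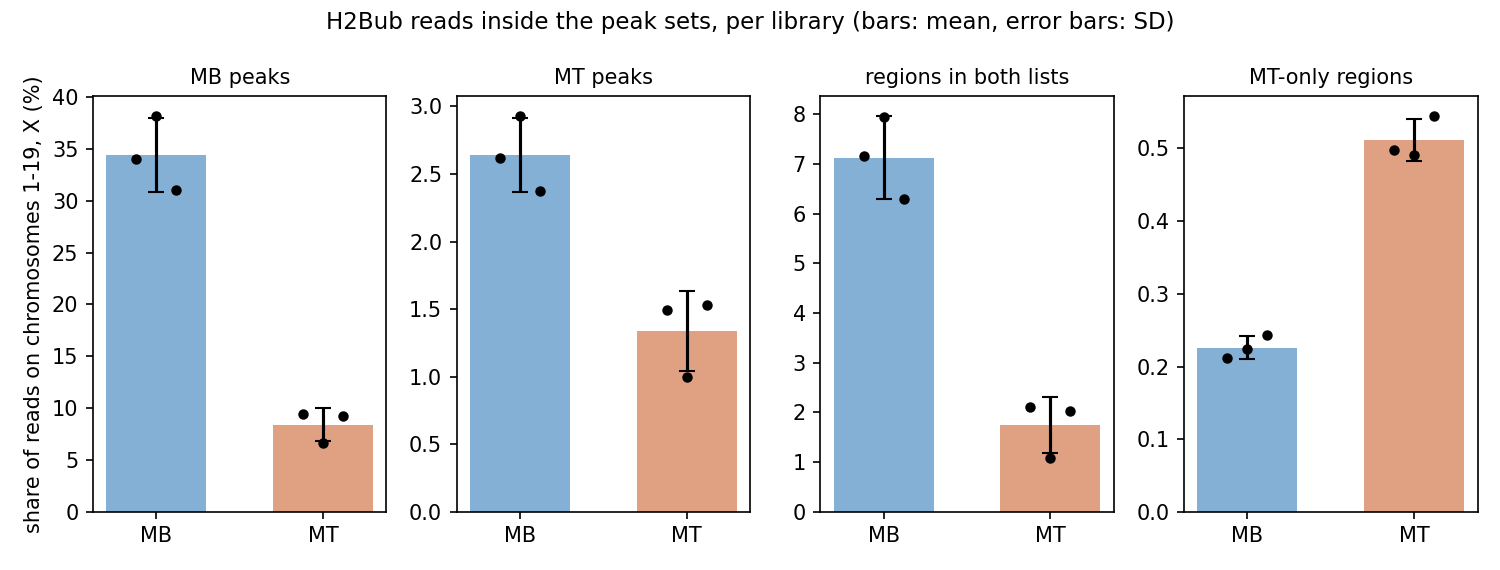
Share of the reads on chromosomes 1 to 19 and X (%, y axis) that fell in MB peaks, MT peaks, regions in both lists and regions in the MT list only, for myoblasts (MB) and myotubes (MT); points are libraries, bars are means and error bars are SD (n = 3). The MB peaks held 31.0% to 38.1% of myoblast reads and 6.63% to 9.42% of myotube reads, and the 4 panels have different scales.

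The H2Bub signal was lower in myotubes over nearly every myoblast domain. The domains were built from MB peaks, so this direction follows in part from their choice. Of the 5326 domains, 5321 were lower in myotubes, 0 were higher and 5 were not called, with a median log2 fold change of -1.74 (limma voom, adjusted p under 0.05). The domain at chromosome 4, 154864343 to 154933654 (69.3 kb), had the largest loss, from 378 ± 45.5 reads per 1000000 reads (RPM) in myoblasts to 42.7 ± 11 RPM in myotubes (SD, n = 3; log2 fold change -3.19, SE 0.29, limma adjusted p = 5.826e-11). The domain at chromosome X, 166391723 to 166409591 (17.9 kb), had the smallest difference, with 29.4 ± 4.73 against 26.1 ± 11.4 RPM (log2 fold change -0.30, SE 0.25, limma adjusted p = 0.2445). Median log2 fold changes were -1.55 for domains of 10 to 20 kb, -1.87 for 20 to 50 kb, -2.01 for 50 to 100 kb and -1.93 for 100 kb or longer. At least 1 MT peak lay in 38.5% of the domains of 10 to 20 kb and in 97.8% of the 91 domains of 100 kb or longer, shares that rise with length alone and for which no chance value was computed. With background scaling the median was -2.45 and all 5326 domains were lower.

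Averaged over the outer 2 kb, myoblast density was lower than in the domain interior, whereas the 2 myotube means were close. Along the profile, density in each library had a local maximum in the first 250 bp inside the edge: in MB replicate 1 it was 7.60 there, 6.23 in the next bin and 8.22 in the bin just under 5 kb. The same 3 bins had 2.15, 1.92 and 1.86 in MT replicate 1 and 1.66, 1.47 and 1.36 in MT replicate 2. Domains begin and end at the boundary of an MB peak, so the first bin inside lies mostly in a peak. Later bins mix peaks and gaps, so the maximum in myoblasts follows from how the domains were made. In myoblasts the outer 2 kb had 7.13 ± 1.00 times the density outside all peaks and the interior, more than 3 kb from an edge, 9.51 ± 1.55 times (SD, n = 3). In myotubes the values were 1.73 ± 0.277 and 1.77 ± 0.353. The excess at the edges over that in the interior was 0.722 ± 0.0213 in myoblasts and 0.99 ± 0.126 in myotubes (exact permutation test, two-sided, n = 3, p = 0.1). MT replicate 2, the library with the lowest share of reads in MB peaks, had the highest of these ratios (1.13), against 0.902 and 0.934 in the other MT libraries.

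**Figure D2:**
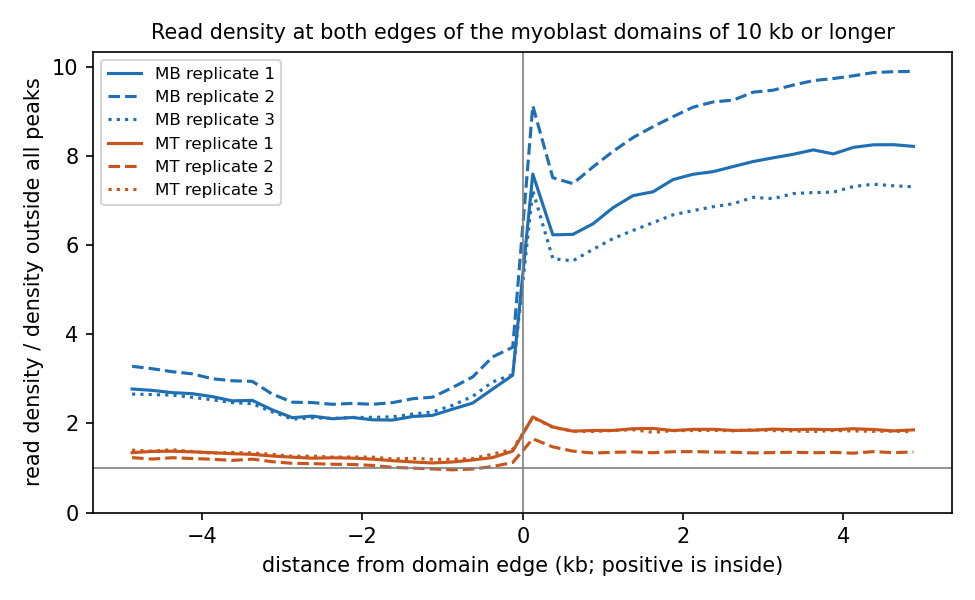
Read density relative to the density outside all peaks (y axis) against the distance from the edge of the 5326 myoblast domains (x axis, kb, both edges combined, positive inside), 1 line per library in 250 bp bins. The means of the whole interior, which extends past the 5 kb drawn, were 8.06 to 11.1 in the myoblast libraries and 2.00, 1.36 and 1.94 in MT replicates 1, 2 and 3.

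The signal was also lower region by region, though these regions rest on the same peaks and reads and are not separate support. Of 63954 peak regions with enough reads, 63125 were lower in myotubes and 12 higher, with a median log2 fold change of -2.07 (limma voom). Regions in the MB list only were lower in 54362 of 54685 cases and higher in 0, and regions in both lists were lower in 8728 of 9205 and higher in 0. A region could pass the floor on its 3 myoblast libraries alone, so these shares depended in part on the floor. Without it, 144395 of 179359 MB-only regions (80.5%) and 9011 of 11310 regions in both lists (79.7%) were lower, and 0 were higher. The largest loss was at chromosome 18, 56870500 to 56871983, with 10.2 ± 0.0502 RPM in myoblasts and 0.471 ± 0.0643 in myotubes (SD, n = 3; log2 fold change -4.37, SE 0.40, limma adjusted p = 7.678e-08). A neighbouring region at chromosome 18, 56874208 to 56876690, had a log2 fold change of -4.06. The other leading losses were at chromosome 2, 91381399 to 91382023 (-4.17), chromosome 4, 154870040 to 154870867 (-4.03), inside the domain named above, and chromosome 17, 66146153 to 66148118 (-3.97).

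Among the peak regions that passed the floor, gains were few and shallow. None of the 12 higher regions had a mean of 50 reads per library, so no gained region met the naming rule; the leading pair is given here after its values were seen. The region at chromosome 8, 64297035 to 64297870, had 0.0779 ± 0.068 RPM in myoblasts and 1.61 ± 0.46 in myotubes (SD, n = 3; log2 fold change 3.92, SE 0.71, limma adjusted p = 3.158e-05). The region at chromosome 6, 24552632 to 24553385, rose from 0.245 ± 0.105 to 1.67 ± 0.355 (SD, n = 3; log2 fold change 2.85, SE 0.58, limma adjusted p = 0.0001231). All 12 belonged to the MT-only regions, of which 64 of 11685 passed the floor and 35 were lower (median log2 fold change -1.38). This balance changed when 1 library was left out at a time, with a floor that asked for 2 libraries instead of 3. Then 72 to 155 passed, with medians of -1.38 to 0.20. Without MT replicate 2, 44 of 144 were higher and 37 lower. The effect of the library left out was not told apart from that of the lower floor. Without the floor, 5817 of the 11685 MT-only regions were higher and 50 lower, so the number of gains depended on the floor. These regions were chosen for a peak in the MT list only, so that direction follows in part from their choice. With background scaling 2 regions were higher, and leaving out 1 library at a time gave 8 to 52. With TMM factors taken over the peak regions themselves, which by construction removes a change shared by all regions (median log2 fold change 0.04), 3862 were higher and 2280 lower.

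Across 10 kb windows, those with MB peaks lost reads and the rest of the genome gained a share of them. Of 233817 windows, 30702 were lower and 165798 higher in myotubes, with a median log2 fold change of 0.78. Windows with MB peaks only were lower in 20663 of 24409 cases, and windows with peaks of both lists in 8137 of 9214. Windows with MT peaks only were higher in 6907 of 8490 cases, and windows without any peak in 158777 of 191704, so the rise was about as common with an MT peak as without. Background scaling moved the median to 0.09 and gave 43891 lower and 5146 higher windows, so 89.5% of called windows were lower against 15.6% with total reads. The windows with MB peaks only were then lower in 23963 of 24409 cases, windows with MT peaks only were higher in 402 and lower in 822 of 8490, and windows without any peak were higher in 4744 and lower in 10045 of 191704.

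The windows that rose most lay in a few stretches of several windows. The window at chromosome 8, 64290001 to 64300000, rose from 2.83 ± 1.07 to 14.3 ± 6.75 RPM (SD, n = 3; log2 fold change 2.19, SE 0.29, limma adjusted p = 1.108e-07), and chromosome 8, 64240001 to 64250000, had a log2 fold change of 1.75. Windows at chromosome 9, 79700001 to 79710000 (1.88), chromosome 16, 25840001 to 25850000 (1.82), and chromosome 16, 25780001 to 25790000 (1.71), followed. All 5 also rose with background scaling, by a log2 fold change of at least 1.007. The lowest window, chromosome 18, 56870001 to 56880000, fell from 65.3 ± 4.32 to 4.11 ± 0.869 RPM (SD, n = 3; log2 fold change -3.95, SE 0.32, limma adjusted p = 2.182e-10). It was followed by windows at chromosome 6, 83870001 to 83880000 (-3.79), chromosome 6, 113040001 to 113050000 (-3.74), chromosome 4, 154870001 to 154880000 (-3.73), and chromosome 2, 91370001 to 91380000 (-3.67).

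**Figure D3:**
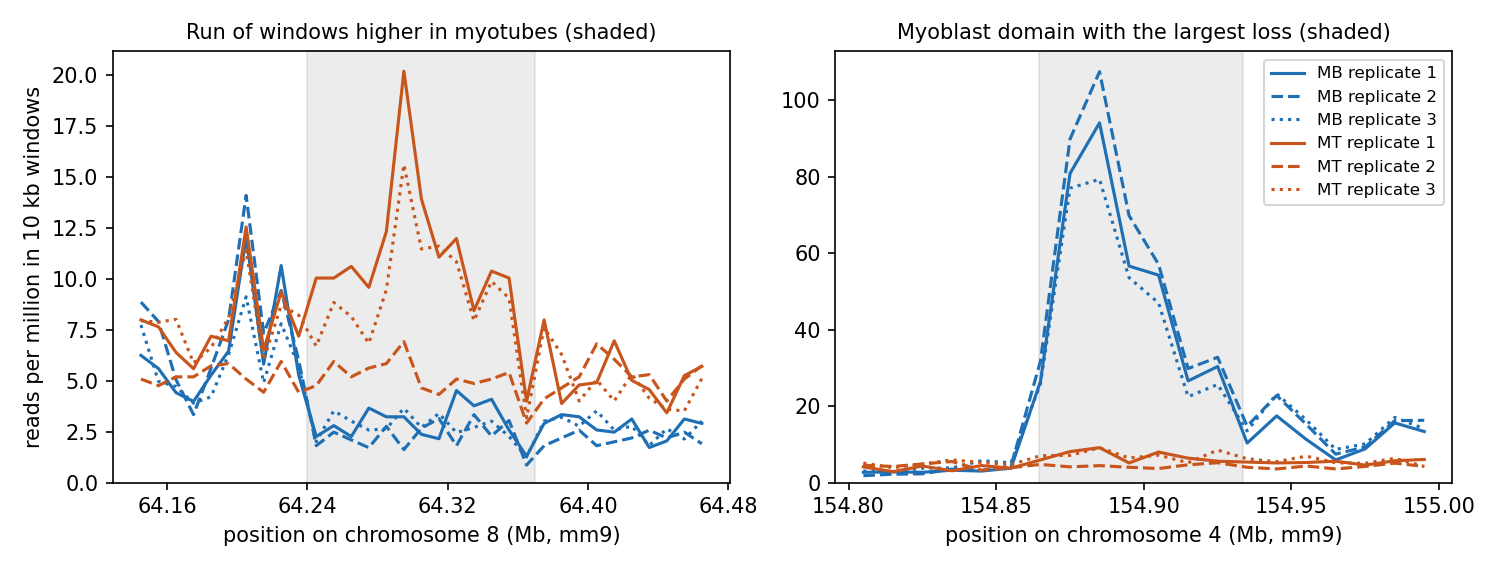
Reads per 1000000 reads (RPM) in 10 kb windows (y axis) along chromosome 8 and chromosome 4 (x axis, Mb, mm9), 1 line per library; shading marks the run of higher windows at 64240001 to 64370000 and the domain at 154864343 to 154933654. Myotube lines lie above myoblast lines in the first stretch, least so in MT replicate 2, and far below them in the second; the y axes differ.

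Most MT peaks lay where myoblasts also had H2Bub. Of the 25743 MT peaks on chromosomes 1 to 19 and X, 14055 overlapped an MB peak by at least 1 bp (54.6%, Wilson interval 54.0 to 55.2). Random placements gave a mean of 6.35% and at most 6.96% in 1000 draws. Conversely, 6.25% of MB peaks overlapped an MT peak. When at least 50% of both peaks had to be shared, 11.1% of MT peaks overlapped.

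The MT peaks without an MB peak were unevenly spread over the chromosomes. Chromosomes 10 and 15 carried 27.1% of them, against 10.6% of MB peaks and 9.04% of covered windows. Chromosome 15 had 18.2 and chromosome 10 had 10.6 such peaks per Mb, whereas chromosome 11 had 5.68 and chromosome 7 had 0.63. These are counts from 1 list, with no replicate error.

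**Figure D4:**
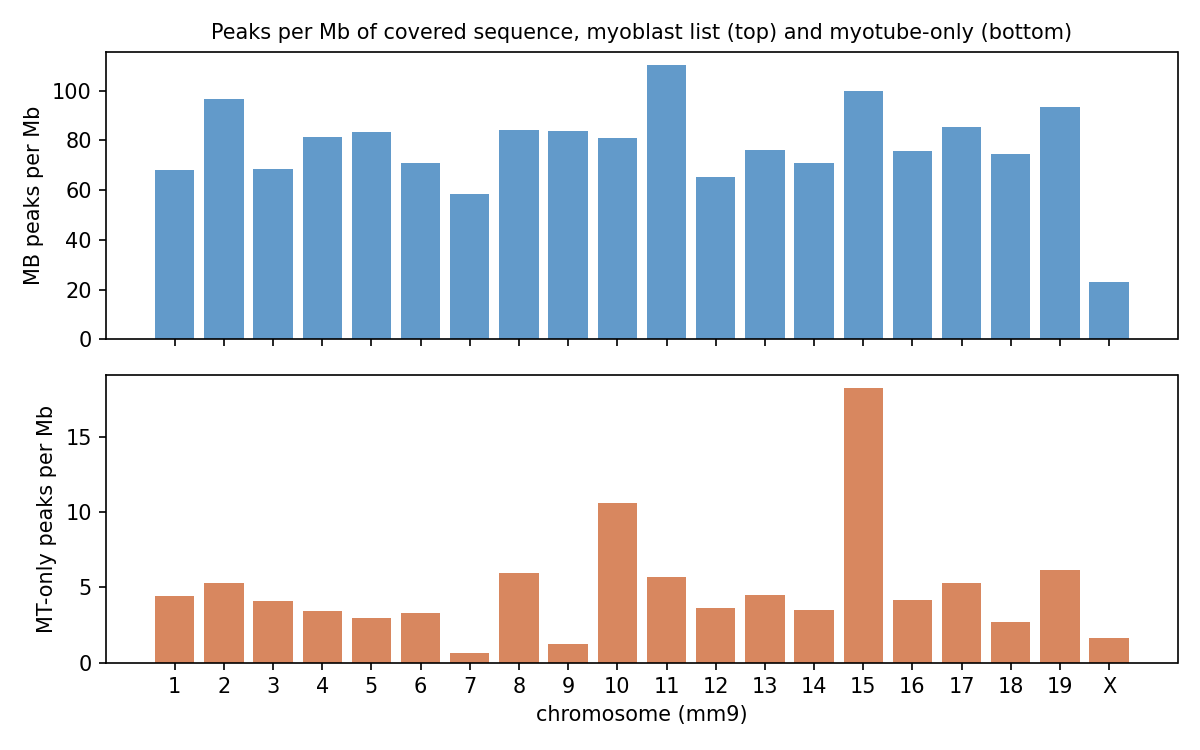
MB peaks per Mb (top) and MT-only peaks per Mb (bottom) of covered sequence (y axes) on each chromosome (x axis), from 1 peak list per group. Chromosome 15 stands at 18.2 and chromosome 10 at 10.6 MT-only peaks per Mb.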

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

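Both results here are reads on sequences outside the comparisons, above the 3 counts that a count of 0 allows, and were looked at only after the data were seen. Reads on the mitochondrial genome were at 14.1 ± 5.31 per 1000000 reads in the myotube libraries and 1.10 ± 0.805 in the myoblast libraries (SD, n = 3; 423 against 34 reads; exact permutation test, two-sided, p = 0.1), a ratio of 12.8 where reads outside peaks rose 1.39 times, and 3 reads in all lay between positions 5000 and 10000. Reads on unplaced contigs were at 928.68 ± 50.8 per 1000000 reads in myotubes and 809.55 ± 43.2 in myoblasts (SD, n = 3; exact permutation test, two-sided, p = 0.1).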

How the results depend on the processing

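Over peak regions, most calls were lower in myotubes with total reads or background scaling, with each library left out and with each other setting tried except TMM over the regions, where 6142 were called, 3862 higher and 2280 lower; that scaling removes a shared change by construction. The 5 named lower regions and the 10 named windows kept their direction and stayed past the threshold under each alternative tried on them. Background scaling gave 2 higher regions, and for windows 49037 calls, 5146 of them higher. Without the floor 159273 of 202354 regions were called, 5817 higher and 153456 lower. The floor had retained 64 of 11685 MT-only regions and 54685 of 179359 MB-only regions. Leaving it out thus changed the mix of regions tested as well as their number. With 1 library left out, 62149 to 84103 regions were called (62128 to 84078 lower and 8 to 52 higher), of 63604 to 91942 tested. In these fits the floor asked for 1 library fewer, so the libraries and the floor changed together. The 12 higher regions became 37, 21 and 25 without MB replicates 1, 2 and 3, and 25, 52 and 8 without MT replicates 1, 2 and 3. For windows the same range was 169707 to 190883, with 142025 to 160811 higher and 27682 to 30224 lower, and for the share of reads in MB peaks -27.6 to -24.1 points. Windows of 50 kb gave 45753 calls, 37557 higher and 8196 lower, being fewer by construction. Chosen after the data were seen, background scaling without MT replicate 2 called 91138 regions, 91127 lower and 11 higher, and 45191 windows, 3809 of them higher. The overlap of MT with MB peaks was 11.1% when 50% of both peaks had to be shared and 51.3% when 50% of the MT peak had to be. The fall to 11.1% thus came mostly from the requirement on the MB peak. MB peaks were wider, with a mean of 541 bp against 306 bp for MT peaks. The replicate block called 62901 regions (62889 lower, 12 higher) and 196910 windows; with background scaling, chosen later, it called 63859 regions, 2 of them higher, and 51635 windows, 6908 of them higher. Deviations of same-numbered libraries were weakly correlated (0.05, -0.015 and 0.054 over regions, 0.001, -0.169 and 0.15 over windows). Differently numbered libraries had -0.066 to 0.021 over regions and -0.243 to 0.207 over windows. The 2 highest values over regions were thus same-numbered, and replicate 3 was the deepest library in both groups. A batch shared by number is not excluded. Not every library correlated best with its own number, so the numbers were not taken to pair the samples. Thinning, limma-trend, shifted positions and the upper 50% of peaks by width moved no total of higher or lower calls by over 1.5 times; among MT-only regions, 12 higher became 7 with thinning and 8 with shifted positions, and 35 lower became 22 with the upper 50%. Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, called as many regions (63137) and windows (196500), and the highest of the others was 0; 10 splits are too few for a share under 0.05. Removing duplicates gave no other value because no position was repeated, and the count-model alternatives and those for genes, gene lists and gene bodies were not run. Depth limits the MT-only regions most, since 64 of 11685 passed the floor.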

Other observations

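The recovery, myotube-background and MT replicate 2 tests below, and the 36 choices of libraries, were added after the first tests had been seen; the MT replicate 2 test was chosen after the plot of the chromosome 8 stretch, and the rule that all 36 choices must agree came after the first choice was seen. Beyond the comparisons, the spacing of nucleosomes outside peaks was 193 ± 2.95 bp in myoblasts and 192 ± 0.503 bp in myotubes (SD, n = 3; exact permutation test, two-sided, p = 0.7), so no difference was detected with 3 libraries. The stretches that hold the 5 named higher windows were denser relative to their local background in myotubes than in myoblasts. The stretch at chromosome 8, 64240001 to 64370000, held 26 MT peaks and had 0.899 ± 0.09 times its local background in myoblasts and 1.58 ± 0.403 times in myotubes (SD, n = 3). The stretches at chromosome 16, 25740001 to 25860000 (1.04 ± 0.0939 against 1.45 ± 0.205), and chromosome 9, 79670001 to 79730000 (0.7 ± 0.12 against 1.44 ± 0.265), held 9 and 4 MT peaks. These 3 were taken because they hold the windows named in the report, not as the highest of the 97 runs. In them every myotube library lay above every myoblast library, as in 72 of the 97 runs. The runs were called higher on these same libraries, so that order follows in part from their choice. MT replicate 2 was the lowest myotube library in the 3 stretches (1.12, 1.22 and 1.13), as in 14 of the 31 runs with an MT peak and 19 of the 66 without. Higher myotube means were seen at chromosome 17, 7770001 to 7800000 (1.92, with MT replicate 2 highest at 2.03), chromosome 17, 3010001 to 3040000 (1.69, with 0 MT peaks), and chromosome 13, 83740001 to 83780000 (1.60).

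The lower signal over the myoblast domains may be a loss of H2Bub on chromatin or a weaker immunoprecipitation that dilutes one profile with background reads. Dilution that acts evenly would leave each domain the same share of its excess. However, the 10% of domains that kept most in replicate 1 kept a median of 21.2% in replicate 3, and the 10% that kept least 3.66%. This was a ratio of 5.78 where under 1.5 was predicted. Replicate 2, which kept a median of 2.43% against 8.59% and 9.57%, was left out of this ratio. Since the numbers were not taken to pair the libraries, all 36 choices were run and gave 2.30 to 6.31. That bound took even read recovery for granted, and stretches of 20 kb without peaks ranged from 0.515 to 1.30 times their local background between their own lowest and highest 10%, picked and measured alike. The recovery that diluted domains would need spread 1.39 times as far as that, within the predicted 1.5. The 36 choices gave 0.386 to 1.53 (median 0.738), with 1 over 1.5 and 0 over the 2 that would speak against uneven recovery. Values were 1.16 to 1.53 without MT replicate 2, 0.652 to 0.814 when domains were picked in it and 0.386 to 0.49 when it was measured. The spread thus varied with 1 library, which the prediction did not cover, and the choices reuse the same 6 libraries. Dilution with uneven recovery therefore stays open. Without an input or spike-in among the samples used here, the size of the loss cannot be told apart from the efficiency of the immunoprecipitation, and a biological loss stays open.

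The runs of higher windows after background scaling could be H2Bub gained in myotubes. Of 97 runs of 3 or more windows, 4 stood over 1.5 times local background in myotubes and under 1.5 times in myoblasts, where even dilution predicted 0; 1 of these, at chromosome 17, 7770001 to 7800000, lay just under the bound at 1.495. That bound too took even read recovery for granted. Of 96707 stretches of 20 kb without peaks, 2172 (2.25%) also had a myotube mean over 1.5 times local background. These stretches were shorter than the runs and had no limit on myoblast density, so they are not a matched comparison. The 4 runs therefore do not decide. Regions recovered well but low in H2Bub stay open as a source, since no value here measures recovery apart from H2Bub. Such regions would be at least as high in MT replicate 2, the most diluted library: its median ratio to the other myotube libraries was 0.972 (bootstrap interval 0.93 to 1.00) in the 31 runs with an MT peak and 1.00 (0.985 to 1.02) in the 66 without. The runs were called on all 3 myotube libraries, which draws these ratios toward 1, so for both kinds of runs gain and dilution cannot be told apart.

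The gathering of MT-only peaks on chromosomes 10 and 15 may reflect more background reads there, as extra copies in the cell line would give. The share of MT-only peaks in the top 10% of myoblast background was 24.8%, over the 20% predicted, but MB peaks, of which 10.6% lie on these chromosomes, reached 29.2%, so that test does not decide. Across the 20 chromosomes, myoblast background went with MT-only peaks per Mb (Pearson r 0.742, permutation p = 0.0004; Spearman rho 0.77, permutation p = 0.00015, adjusted over 2 relations 0.00015; r 0.699 without the 2 chromosomes farthest from the median), but more closely with MB peaks per Mb (r 0.902, permutation p = 1e-05, the smallest that 100000 permutations can give; rho 0.857, permutation p = 2e-05, adjusted 4e-05), so it is not particular to MT-only peaks. The rate of MT-only peaks per level of myotube background on the other chromosomes predicted 72.6% of the 3124 on these chromosomes that had a local background, between the 75% that background alone would need and the 50% that would exclude it. No input was at hand to measure copies, and a difference in H2Bub there stays open, untested.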
